A study of Mus musculus with 2 samples.

How the data were processed

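The series holds 2 RNA-seq libraries of the mouse macrophage line RAW264.7, 1 from 2D and 1 from 3D culture. Per the labels' protocols, total RNA of untreated cells was extracted with TRIzol and libraries were made with an Illumina TruSeq stranded kit that selects polyadenylated RNA and marks the strand. The deposited values are counts of reads per Ensembl gene, which the authors made with Trimmomatic, HISAT2 and HTSeq on genome build mm10, per the submitters' processing notes. Versions, settings, the strand option of the counting and the annotation release are not given in the sources used here. The values in the deposited tables were whole numbers whose totals differed between the libraries, 14371084 in the 2D library and 16652503 in the 3D library, and no row lacked a gene. How the counting treated reads that match several places or overlapping genes is also not given, so counts of genes with near-identical copies, and of overlapping or antisense genes, are uncertain.

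Of 52550 gene identifiers, 52403 (99.7%) matched the GENCODE M21 annotation of mm10, which gave symbols, positions, gene classes, exon lengths and the GC content of the longest transcript, and 147 did not match. Counts were scaled with the TMM factors of edgeR 4.0.16 in R 4.3.3, which were 1.231 for the 2D library and 0.813 for the 3D library. A gene was measured where its mean over both libraries reached 1 TMM-scaled count per 1000000 (CPM), which left 11673 genes. The main value was the ratio of CPM in the 3D library over the 2D library, with an exact (Clopper-Pearson, conditional on the sum of the counts) 95% counting interval. A library with 0 counts was set to a floor of 3 counts, which makes the ratio a bound; this applied to 9 measured genes, and no ratio was formed where both libraries were at or under the floor. A ratio of at least 2 in either direction was counted as a difference of size. No test across replicates and no p-value was possible with 1 library per culture method, and libraries could not be left out in turn. Shares of counts have Wilson intervals.

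Gene lists, 47 on macrophage and general cell biology and 8 of markers of other cell types, were fixed together with the groups, the ratio, the size rule and most alternatives before the data were examined. For each list with at least 4 measured members, the median log2 ratio was placed among the medians of 10000 random lists of the same size matched on mean expression in 50 bins. A list was said to lie beyond the limits in the outer 2.5% on either side. Members of a list can move together, which random lists do not, so these percentiles describe the libraries and are not p-values. Genes were named by a rule also fixed beforehand: the 12 highest and the 12 lowest ratios, ranked by the interval bound nearest to 1 among named genes with a mean of at least 5 CPM, up to 4 members of each list at least 2-fold different, and a set of landmark genes. The rule left pseudogenes, mitochondrial genes and genes without a given name out of the 24 extremes. Not all genes it picks are described, and a few genes that complete a list or a count are named outside it.

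The alternatives were the size factors of DESeq2 1.42.0, total counts, upper-quartile scaling, no filter, a mean of at least 5 CPM, a pseudocount of 1 CPM, thresholds of 1.5-fold and 4-fold, the interval bound in place of the ratio, thinning of both libraries to 0.5 of the smaller total, protein-coding genes only, and random lists also matched on exon length. Further alternatives were chosen after seeing the data. The log2 ratio was adjusted for GC content, exon length and mean expression with natural cubic splines of 4 degrees of freedom (patsy 1.0.2, numpy 2.4.6), for which 99.9% of measured genes had values, and libraries were scaled so that the median log2 ratio of the reference genes was 0. The adjustment removes any biological difference that runs along these properties together with a technical one. A list of genes for plasma proteins made by the liver was also drawn up after seeing the data.

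The code was tested on simulated counts with 200 changed genes and known folds, with the means and depths of these libraries. With no trend, 100% of genes changed 3-fold or 4-fold were recovered at the 2-fold rule, as were 60% of those changed exactly 2-fold, and 0.18% of unchanged genes were called. With a GC trend added, 76% of genes changed 3-fold and 86% of those changed 4-fold were recovered, and 20.45% of unchanged genes were called without the adjustment against 0.33% with it. The counting intervals held the true ratio for 95.8% of genes without and 95.2% with the trend. Simulated counts were Poisson draws scaled to total counts, and the added trend was linear in GC content alone. The coverage and the removal of that trend follow from this model, so they check the code and not the data. TMM scaling, spread beyond counting error and trends along exon length or expression were not simulated. Of 200 simulated random lists of 30 genes, 7.0% and 3.0% lay beyond the percentile limits, where 5% is nominal. Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the remaining steps.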

Results

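Messenger RNA was profiled in RAW264.7 cells, a mouse macrophage line transformed by Abelson murine leukaemia virus, that had been kept without treatment in 2D or in 3D culture. The comparison asks how the transcriptome of this line differs between the culture methods; how the 3D culture was made is not given in the sources used here. Each culture method was represented by 1 library, with 14371084 counts for the 2D library and 16652503 for the 3D library. A gene with 0 counts could thus have reached 0.209 counts per 1000000 total counts in the 2D library and 0.18 in the 3D library, before TMM scaling. At least 1 count was present for 18580 genes in the 2D library and for 15777 in the 3D library, or 15546 when the 3D library was thinned to the depth of the 2D library. The 20 most abundant genes held 9.54% of the counts in the 2D library and 15.1% in the 3D library. With 1 library per culture method, every difference lacks a replicate check, and no p-value was computed. The 95% intervals given with ratios are exact intervals for counting error only, and they treat reads as independent. Reads without molecular identifiers are not independent molecules, so the intervals can be too narrow even for that error. They hold no spread between replicate cultures. Positions refer to mouse genome build mm10 (GRCm38).

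Genes for glycolysis and of the NRF2 antioxidant programme were higher in the 3D library, and genes for mitosis and several nuclear noncoding RNAs were lower. Heme oxygenase Hmox1 stood at 222 TMM-scaled counts per 1000000 (CPM) in the 2D library and 2829 in the 3D library. The lipid droplet coat protein Plin2 stood at 182 and 2548 CPM. The proliferation marker Mki67 went the other way, with 618 CPM in the 2D library and 180 in the 3D library, as did the paraspeckle RNA Neat1, with 1376 and 60.7 CPM. Among 11673 measured genes, 2181 were at least 2-fold higher in the 3D library, 2426 were at least 2-fold lower and 7066 lay between. The higher genes made up 47.3% of those 4607 calls under TMM scaling but 13.3% when libraries were scaled to total counts only, with 657 higher and 4292 lower, and 8.1% when they were scaled to 22 reference genes, with 416 higher and 4704 lower. The median log2 ratio of all genes was 0.05 under TMM scaling, -0.56 under total counts and -0.72 under the reference genes. Medians of gene lists are therefore given relative to the all-gene median.

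The ratio followed transcript composition across protein-coding genes. Over 10538 protein-coding genes in 10 bins of GC content, the median log2 ratio ran from -1.28 in the bin with the lowest GC content to 0.96 in the bin with the highest. GC content alone accounted for 35.3% of the variance of the log2 ratio, exon length for 11%, mean expression for 10.4% and all 3 together for 47.8%. After adjustment for these 3 properties, a step chosen after seeing the data, 1227 genes were at least 2-fold higher and 1138 at least 2-fold lower. Of the 2181 genes called higher before adjustment, 669 stayed at least 2-fold higher, 1301 kept the direction below 2-fold and 211 turned. The corresponding numbers for the 2426 lower genes were 904, 1263 and 256, with 3 lacking a GC value. Of the 189 genes picked by rule as extremes, as the strongest members of each list or as landmarks, 131 were at least 2-fold higher and 50 lower, and after adjustment 56 and 33 of these stayed so. Scaling to total counts lowered their log2 ratios by 0.6 and kept 98 and 50 of them at least 2-fold different, and reference gene scaling lowered them by 0.77 and kept 77 and 50. Folds of single genes are given under TMM scaling and before adjustment, and adjusted log2 ratios are added for those named below that did not keep a 2-fold difference.

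**Figure D1:**
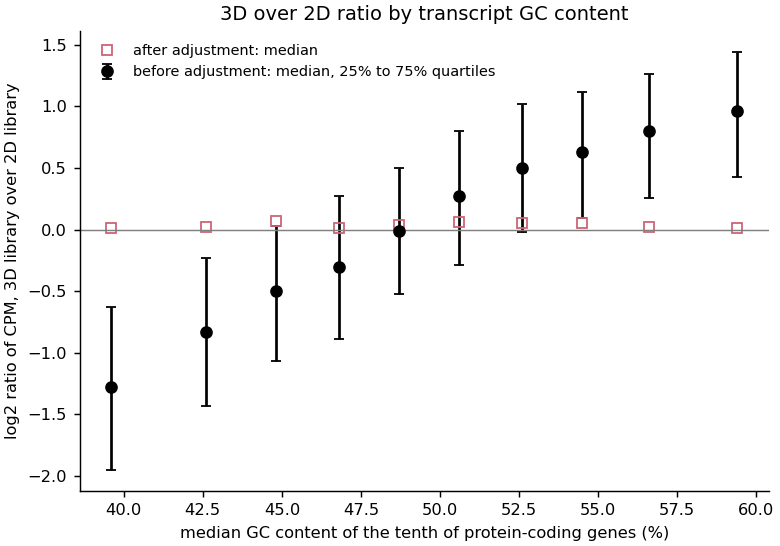
Median log2 ratio of CPM in the 3D library over the 2D library (y axis) for 10 equal bins of protein-coding genes ordered by transcript GC content in percent (x axis). Filled circles are medians with bars from the 25% to the 75% quartile before adjustment, running from -1.28 to 0.96, and open squares are medians after adjustment, all between 0.01 and 0.07.

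Among the genes with the highest ratios, the small heat shock protein gene Cryab (ENSMUSG00000032060, chromosome 9, 50751325 to 50756636) had 20 counts in the 2D library and 881 in the 3D library, a 57.6-fold difference (95% interval 37.0 to 94.7). The matrix metalloproteinase gene Mmp9 (ENSMUSG00000017737, chromosome 2, 164940780 to 164955850) was 21.5-fold higher in the 3D library (18.4 to 25.3). Plin2 (ENSMUSG00000028494, chromosome 4, 86648386 to 86670060) was 14.0-fold higher (13.5 to 14.6), and Hmox1 (ENSMUSG00000005413, chromosome 8, 75093621 to 75100589) was 12.8-fold higher (12.4 to 13.2). The immediate early transcription factor gene Egr1 was 9.04-fold higher (8.16 to 10), and Pdpn, which encodes the membrane mucin podoplanin, was 8.26-fold higher (7.49 to 9.13). Phosphoglycolate phosphatase Pgp was 7.95-fold higher, the glutathione transferase gene Gstp1 11-fold, Prss46 11.6-fold, Tmem54 9.49-fold and Ccdc65 11.1-fold; Gstp1 has close paralogs, so its counts are uncertain. Adjusted log2 ratios stayed above 1 for each of these genes, at 4.94 for Cryab, 3.46 for Mmp9, 2.49 for Plin2 and 1.97 for Hmox1. The serum albumin gene Alb had 8 and 232 counts, a 37.9-fold difference (18.9 to 88.8). Other genes for plasma proteins made by the liver, picked after their values were seen, had low counts that differed the same way. Ahsg had 1 count in the 2D library and 38 in the 3D library, Apoa1 had 1 and 24, and Ttr had 0 and 11. Whether these counts, that of Alb included, came from the RAW264.7 cells, from hepatocyte RNA or from reads of another library is not known.

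Nuclear noncoding RNAs were among the genes with the lowest ratios. Neat1 (ENSMUSG00000092274, chromosome 19, 5824708 to 5845478), the scaffold of paraspeckles, was 22.7-fold lower in the 3D library (21.2 to 24.3). Malat1 (ENSMUSG00000092341, chromosome 19, 5795690 to 5802672), which resides in nuclear speckles, was 16.0-fold lower (14.9 to 17.2), and Firre, a nuclear RNA from the X chromosome, was 14.4-fold lower (11.8 to 17.8). Of the protein-coding genes, the F-box gene Fbxo48 was 28.9-fold lower (13.1 to 79.7) and the Schlafen gene Slfn4 17.7-fold lower (12.9 to 25.1). The splicing factor gene Prpf39 was 15.7-fold lower and the inhibitory receptor gene Lilrb4a 12.5-fold lower; Lilrb4a has a close paralog, so its counts are uncertain. Collagen gene Col27a1 was 14.6-fold lower, and Cox17, a copper chaperone for cytochrome c oxidase, was 17.3-fold lower and overlaps another annotated gene. Zfp760 was 19.3-fold lower, the odorant receptor gene Olfr111 20.4-fold and Spaca6 15.8-fold. Adjusted log2 ratios stayed below -2 for all 12 genes, at -4.45 for Neat1, -3.75 for Malat1, -4.00 for Col27a1 and -2.40 for Prpf39.

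**Figure D2:**
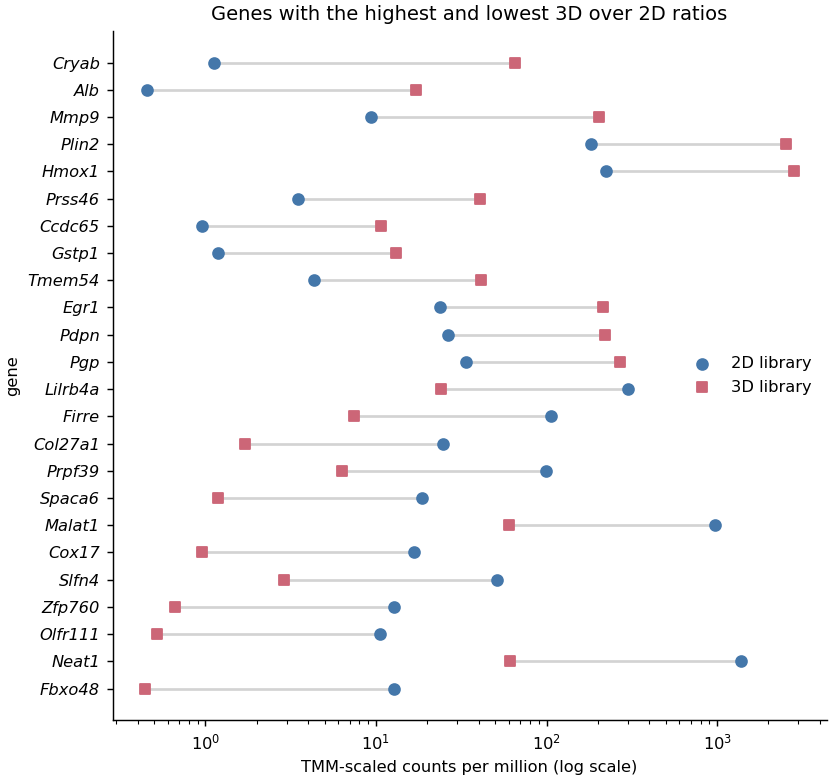
TMM-scaled counts per 1000000 (CPM) on a log axis (x axis) for the 12 genes with the highest and the 12 with the lowest ratio of the 3D library over the 2D library (y axis, ordered by ratio). Circles are the 2D library and squares the 3D library, as for Hmox1 at 222 and 2829 CPM and Neat1 at 1376 and 60.7 CPM.

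Long noncoding RNA classes as a whole were lower in the 3D library. Genes annotated as lincRNA, antisense or TEC (transcripts to be experimentally tested) held 0.818% of the counts in the 2D library (95% Wilson interval 0.813% to 0.822%) and 0.189% in the 3D library (0.187% to 0.191%). Of 382 measured genes of these classes, 249 were at least 2-fold lower and 19 at least 2-fold higher, with a median log2 ratio of -1.72 before adjustment and -0.92 after it. Small nucleolar RNA genes held 824 counts in the 2D library and 119 in the 3D library. Processed pseudogenes went the other way, from 1.30% to 2.28% of the counts.

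Glycolytic enzyme genes formed the list with the highest median before adjustment. Of 21 measured genes, 17 were at least 2-fold higher in the 3D library, 0 were lower, and the median lay 2.00 log2 units above that of all genes. Aldolase Aldoa stood at 1729 CPM in the 2D library and 9600 in the 3D library, a 5.55-fold difference (5.48 to 5.62); glucose-6-phosphate isomerase Gpi1 was 5.28-fold higher and triosephosphate isomerase Tpi1 5.21-fold. Enolase Eno1 was 4.92-fold higher and its near-identical copy Eno1b 5.91-fold, and reads could be shared between them. Random lists matched on expression fell below the glycolysis median in 100% of draws. After adjustment the list median was 0.59 above that of all genes, at percentile 99.98, with 4 genes at least 2-fold higher and 1 lower. Gpi1 (adjusted log2 ratio 1.27) and Gapdh (1.12) stayed above 2-fold, whereas Aldoa (0.40), Tpi1 (0.71), Eno1 (0.41) and Eno1b (0.82) did not. Gapdh has many processed copies, so its counts and its adjusted value are uncertain. Targets of the hypoxia-inducible factors, a list that shares 14 of its measured genes with glycolysis, had 25 of 46 genes higher and 1 lower, with a relative median of 1.18 (percentile 99.99) and an adjusted one of 0.49 (percentile 100), with 7 higher and 1 lower after adjustment. Vegfa, which encodes a growth factor for blood vessels and belongs to this list, was 1.28-fold lower in the 3D library (1.21 to 1.35). Of 9 genes of the pentose phosphate pathway, 5 were higher and 1 was lower; the relative median of 1.24 (percentile 99.21) became 0.25 (percentile 88.4) after adjustment, with 1 higher and 0 lower. Its members Pgls, Tkt, Pgd and G6pdx were 4.05-fold, 3.83-fold, 3.80-fold and 3.21-fold higher, with adjusted log2 ratios of 0.75, 0.79, 1.44 and 0.71.

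Genes of the NRF2 antioxidant programme were also higher in the 3D library. In the NRF2 and glutathione list, 19 of 33 genes were at least 2-fold higher and 0 lower, with a relative median of 1.20 (percentile 99.99) and an adjusted one of 0.33 (percentile 99.68), with 9 higher after adjustment. Besides Hmox1 and Gstp1, the ferritin light chain gene Ftl1 was 6.58-fold higher (adjusted log2 ratio 0.76), although it has processed copies in the genome. Gsta3, a glutathione transferase abundant in liver, had 1 count in the 2D library and 66 in the 3D library, an 86.3-fold ratio with an interval of 15.0 to 3458, and the same question on the source of the counts applies to it. In the iron and heme list, 8 of 17 genes were higher and 3 lower, among them biliverdin reductase Blvrb at 5.20-fold (4.69 to 5.78) and the heme transporter gene Slc48a1 at 4.77-fold (4.52 to 5.04), with adjusted log2 ratios of 1.52 and 0.90. The relative median of that list was 0.70 (percentile 82.92) before adjustment and 0.58 (percentile 99.95) after it, with 4 higher and 0 lower. It shares Hmox1, Fth1, Ftl1, Blvrb and Slc48a1 with the NRF2 and glutathione list. The NRF2 list also holds G6pdx, Pgd, Tkt and Taldo1 of the pentose phosphate pathway, so the results of these lists are not independent. Metallothionein Mt1 was 4.24-fold higher and the zinc transporter gene Slc39a10 2.14-fold lower in a list of 4 measured genes with a relative median of -0.62 (percentile 9.7); their adjusted log2 ratios were 0.57 and -0.69.

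None of 55 genes of the G2 and M phase list was 2-fold higher and 24 were at least 2-fold lower, including the mitotic kinesin genes Kif20b (7.87-fold, 6.63 to 9.41) and Cenpe (6.02-fold, 5.30 to 6.86), the kinetochore gene Cenpf (6.62-fold, 5.82 to 7.57) and the condensin gene Smc4 (5.44-fold, 4.93 to 6.02). The relative median was -0.78 before adjustment and -0.70 after it, at percentile 0.0 in each case, while 11 of the genes stayed at least 2-fold lower. Of the 55 genes, 9 lay above the all-gene median before adjustment, among them Plk1 at 1.91-fold, Cdc20 at 1.42-fold and Aurka at 1.33-fold higher. The adjusted log2 ratios of these 3 genes were -0.18, -0.68 and -0.26. Mki67 was 3.44-fold lower (3.29 to 3.59), with an adjusted log2 ratio of -1.80. In the S phase list 12 of 50 genes were lower and 2 higher; its relative median of -0.39 (percentile 0.78) became -0.24 (percentile 2.62) after adjustment, with 8 lower and 0 higher. The chromatin remodeller gene Hells was 5.31-fold lower (4.54 to 6.24) and the helicase gene Blm 3.79-fold lower (3.31 to 4.36), with adjusted log2 ratios of -0.98 and -1.18. Only 4 of 29 replication-dependent histone genes were measured, Hist1h1c at 2.07-fold higher and Hist1h1d at 3.70-fold lower among them. The relative median was 0.50 (percentile 89.5). With so few measured, in libraries of selected polyadenylated RNA, this list gives no reading on S phase. After adjustment Hist1h1c was near equal (log2 ratio 0.06) and Hist1h1d turned direction (0.48). The cyclin-dependent kinase inhibitor gene Cdkn1a was 3.89-fold higher in the 3D library (3.73 to 4.05), with an adjusted log2 ratio of 0.72. Across all 28 measured p53 targets, 4 were higher and 6 lower, with a relative median of -0.08 (percentile 43.46).

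Of 24 macrophage identity genes, 22 were measured, and 12 of these were at least 2-fold higher in the 3D library, with 1 lower. Csf1r, the receptor for macrophage colony-stimulating factor, was 3.06-fold higher (2.98 to 3.14), the lipopolysaccharide co-receptor gene Cd14 4.24-fold (4.10 to 4.39) and the transcription factor gene Cebpb 6.23-fold (5.35 to 7.28). The relative median of 1.10 (percentile 99.58) became 0.13 (percentile 76.95) after adjustment, with 3 genes at least 2-fold higher. Adjusted log2 ratios were 0.34 for Csf1r, 0.64 for Cd14 and 1.26 for Cebpb. The lysosomal glycoprotein gene Cd68 was 3.26-fold higher before adjustment, with an adjusted log2 ratio of -0.12. Adgre1, which encodes F4/80, had a ratio of 1.41 (1.19 to 1.68) under TMM scaling and lay below 1 under total counts and under the reference genes.

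Of the alternative activation list, 8 of 25 genes were measured, and 6 of them were at least 2-fold higher in the 3D library. Il4ra, Myc and Igf1 passed narrowly, at log2 ratios of 1.01, 1.02 and 1.09, so the shift of -0.6 under total counts ends their calls. Tgfb1, which encodes a growth factor that dampens inflammation, was 6.39-fold higher (6.20 to 6.60), and Egr2 was 4.36-fold higher (2.64 to 7.47). Igf1 was 2.12-fold higher (1.68 to 2.69), and the fibronectin gene Fn1 had 10 and 33 counts, but liver cells make its product too, so the source of its counts is open as for Alb. The relative median was 1.0 (percentile 97.91) and 1.43 (percentile 99.89) after adjustment. The arginase gene Arg1, with 2 counts in the 2D library and 4 in the 3D library, and the mannose receptor gene Mrc1, with 0 and 2, were too low to compare. Of the inflammatory landmarks, Nos2, the inducible nitric oxide synthase gene, was 2.29-fold higher in the 3D library (2.03 to 2.58; adjusted log2 ratio 0.66), while the cytokine gene Tnf was 1.90-fold lower (1.71 to 2.12). Il1b had 0 and 1 counts and Il6 had 0 in both libraries. In the list of inflammatory cytokines and effectors, 4 of 13 measured genes were higher and 0 lower, with the interleukin-1 receptor antagonist gene Il1rn at 2.64-fold (2.52 to 2.76) and the prostaglandin E synthase gene Ptges at 3.37-fold (2.72 to 4.19). Its relative median was 0.40 (percentile 92.79), or 0.64 (percentile 99.12) after adjustment, with 4 higher and 1 lower. The lower gene was Tnf, with an adjusted log2 ratio of -1.73. The chemokine genes Ccl3 and Ccl4 were 2.48-fold and 2.79-fold higher, and 3 of 6 chemokines passed 2-fold, with a relative median of 0.99 (percentile 89.36). After adjustment Ccl3 and Ccl4 had log2 ratios of 0.08 and 0.27, and 1 of the 6 passed 2-fold.

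Interferon-stimulated genes had the lowest median of the lists before adjustment, and 11 of 24 measured genes were at least 2-fold lower and 1 was higher. The antiviral synthetase gene Oas2 was 8.70-fold lower (5.73 to 13.8), Samd9l 6.50-fold (3.98 to 11.3) and the double-stranded RNA sensor kinase gene Eif2ak2 4.60-fold (3.78 to 5.65). The relative median was -0.85 (percentile 4.47) before adjustment and -0.52 (percentile 0.65) after it, with 5 lower and 0 higher. Among NF-kB feedback genes, 5 of 18 were higher and 3 lower, with a relative median of 0.40 (percentile 91.89); Nfkb2 was 3.22-fold higher and Nfkbiz 6.26-fold lower. MHC class I genes had 6 of 17 higher and 1 lower (relative median 0.70, percentile 95.22), that being Nlrc5, the transactivator of the class, at 3.87-fold lower. Only 4 of 10 MHC class II genes were measured, and 2 were higher (relative median 1.15, percentile 97.29), the invariant chain gene Cd74 at 2.89-fold and H2-Eb1 at 13 and 54 counts. Adjusted log2 ratios were -0.86 for Samd9l, 0.67 for Nfkb2 and -0.02 for Cd74.

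Receptor, lysosome and lipid genes varied within their lists. For phagocytic, scavenger and Fc receptors, 7 of 26 genes were higher and 1 lower; the relative median of -0.02 (percentile 43.86) became 0.50 (percentile 99.75) after adjustment. The Fc receptor gene Fcgr3 was 3.48-fold higher (3.13 to 3.86). In the lysosome and vacuolar ATPase list, 20 of 49 genes were higher and 1 lower (relative median 0.78, percentile 74.46), with the cathepsin gene Ctsd at 4.25-fold (4.16 to 4.35). Lipid-associated macrophage genes had 8 of 18 higher and 0 lower (0.58, percentile 26.76), with the galectin gene Lgals3 at 6.60-fold (6.45 to 6.75) and the lipid receptor gene Trem2 at 3.05-fold (2.94 to 3.17). Fatty acid synthesis and storage had 11 of 28 higher and 1 lower (0.65, percentile 84.39). In that list Hilpda, an inhibitor of triglyceride breakdown, was 4.27-fold higher (3.92 to 4.65) and the fatty acid elongase gene Elovl6 5.71-fold lower (4.70 to 6.99). For cholesterol synthesis, 10 of 26 genes were higher and 1 lower, with a relative median of 0.59 (percentile 89.63), or 0.28 (percentile 97.85) after adjustment. Cholesterol efflux and LXR targets had 5 of 13 higher and 2 lower (0.55, percentile 87.36), and the exporter gene Abca1 was 11-fold lower (5.40 to 26.1). Autophagy genes had 8 of 28 higher and 2 lower (0.40, percentile 83.03), with the cargo receptor gene Sqstm1 at 4.88-fold (4.75 to 5.01). Complement genes had 2 of 6 higher (0.47, percentile 80.22), C3 at 5.13-fold among them, with the same doubt as for Fn1. Adjusted log2 ratios were 0.30 for Ctsd, 0.84 for Lgals3, 0.79 for Trem2 and 0.82 for Sqstm1.

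In the actin and SRF target list, 23 of 37 genes were at least 2-fold higher and 0 lower, with a relative median of 1.11 (percentile 97.12) that became 0.07 (percentile 73.88) after adjustment. Vimentin gene Vim was 5.28-fold higher (5.21 to 5.35), with an adjusted log2 ratio of 1.56, and Actg1 6.68-fold (6.52 to 6.84), with 1.21. Actb was 2.23-fold higher (2.20 to 2.26) but had an adjusted log2 ratio of -0.36; both actin genes have processed copies in the genome. The integrin and focal adhesion list had 15 of 32 genes higher and 1 lower, with a relative median of 0.91 (percentile 98.68) and an adjusted one of 0.27 (percentile 97.6), with 3 higher and 1 lower. The focal adhesion gene Zyx was 5.91-fold higher (5.58 to 6.27) and the integrin gene Itga4 4.31-fold lower (4.04 to 4.61). Of 23 measured matrix and matrix remodelling genes, 8 were higher and 4 lower (0.50, percentile 88.61). YAP and TAZ targets had 2 of 12 higher and 1 lower (-0.44, percentile 38.29), and TGF-beta response genes had 3 of 15 higher and 3 lower (0.13, percentile 72.11). Osteoclast differentiation genes had 9 of 21 higher and 3 lower, with the fusion gene Dcstamp at 3.00-fold (2.77 to 3.24); the relative median of 0.72 (percentile 92.86) became -0.29 (percentile 4.96) after adjustment. Angiogenic and growth factor genes had 9 of 23 higher and 3 lower (0.54, percentile 90.9), among them the placental growth factor gene Pgf at 6.43-fold higher (4.52 to 9.37). Dendritic cell and migration genes had 3 of 10 higher and 2 lower (0.59, percentile 95.08), with the chemokine receptor gene Ccr1 at 4.07-fold higher (3.77 to 4.39).

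Genes of the unfolded protein response and of the ATF4 response ranked low among genes of like expression. In the unfolded protein response list, 1 of 25 genes was higher and 2 were lower, namely the stress sensor gene Ern1 (2.55-fold lower, 2.22 to 2.94) and Ddit3, which encodes CHOP (2.5-fold lower, 2.13 to 2.95). Its relative median of 0.12 lay at percentile 1.27, because random lists matched on expression had a median log2 ratio of 0.76, and after adjustment it was -0.46 (percentile 0.27). The ATF4 and amino acid response list had 3 of 35 genes higher and 6 lower, with a relative median of -0.17 (percentile 1.52) and -0.53 (percentile 0.0) after adjustment; the cystathionine gamma-lyase gene Cth was 6.21-fold lower (4.38 to 9.04). Heat shock genes had 6 of 21 higher and 1 lower (0.40, percentile 38.62), with the chaperone gene Hspa8 at 3.32-fold (3.27 to 3.38). Apoptosis regulators had 4 of 30 higher and 5 lower (-0.16, percentile 31.42), among them Bak1 at 3.54-fold higher and Cflar at 3.22-fold lower, with adjusted log2 ratios of 0.62 and -1.0. Immediate early genes had 16 of 30 higher and 1 lower; besides Egr1, the AP-1 gene Fosl1 was 4.45-fold higher (3.90 to 5.10). Their relative median of 0.99 (percentile 100) became 0.30 (percentile 96.45) after adjustment, with 9 higher and 4 lower. Arginine and polyamine genes had 6 of 15 higher and 2 lower (0.27, percentile 46.86), with the spermine oxidase gene Smox at 5.31-fold (4.83 to 5.85).

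Of 69 nuclear-encoded oxidative phosphorylation genes, 36 were at least 2-fold higher in the 3D library and 0 lower, with a relative median of 0.97 (percentile 100) that became 0.14 (percentile 95.46) after adjustment, with 7 higher and 1 lower. None of 12 mitochondrially encoded genes reached 2-fold under TMM scaling before adjustment, and their relative median was -0.42 (percentile 0.48). After adjustment it was -0.20 (percentile 21.55), with 2 higher and 1 lower. The mitochondrially encoded genes held 3.04% of the counts in the 2D library and 1.53% in the 3D library. TCA cycle genes had 7 of 25 higher and 0 lower (0.43, percentile 23.43). Cytosolic ribosomal protein genes, many of which have processed copies, had 42 of 76 higher and 0 lower (1.08, percentile 91.34), and their adjusted relative median was 0.06 (percentile 79.46). Ribosome biogenesis genes had 9 of 46 higher and 4 lower (0.18, percentile 28.76), and proteasome genes 13 of 32 higher and 1 lower (0.67, percentile 75.6). Reference genes had 8 of 22 higher and 2 lower, with a relative median of 0.72 (percentile 39.86) that was -0.16 (percentile 20.96) after adjustment; Gapdh was 4.07-fold higher (3.85 to 4.30), with reads possibly shared with its many processed copies.

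**Figure D3:**
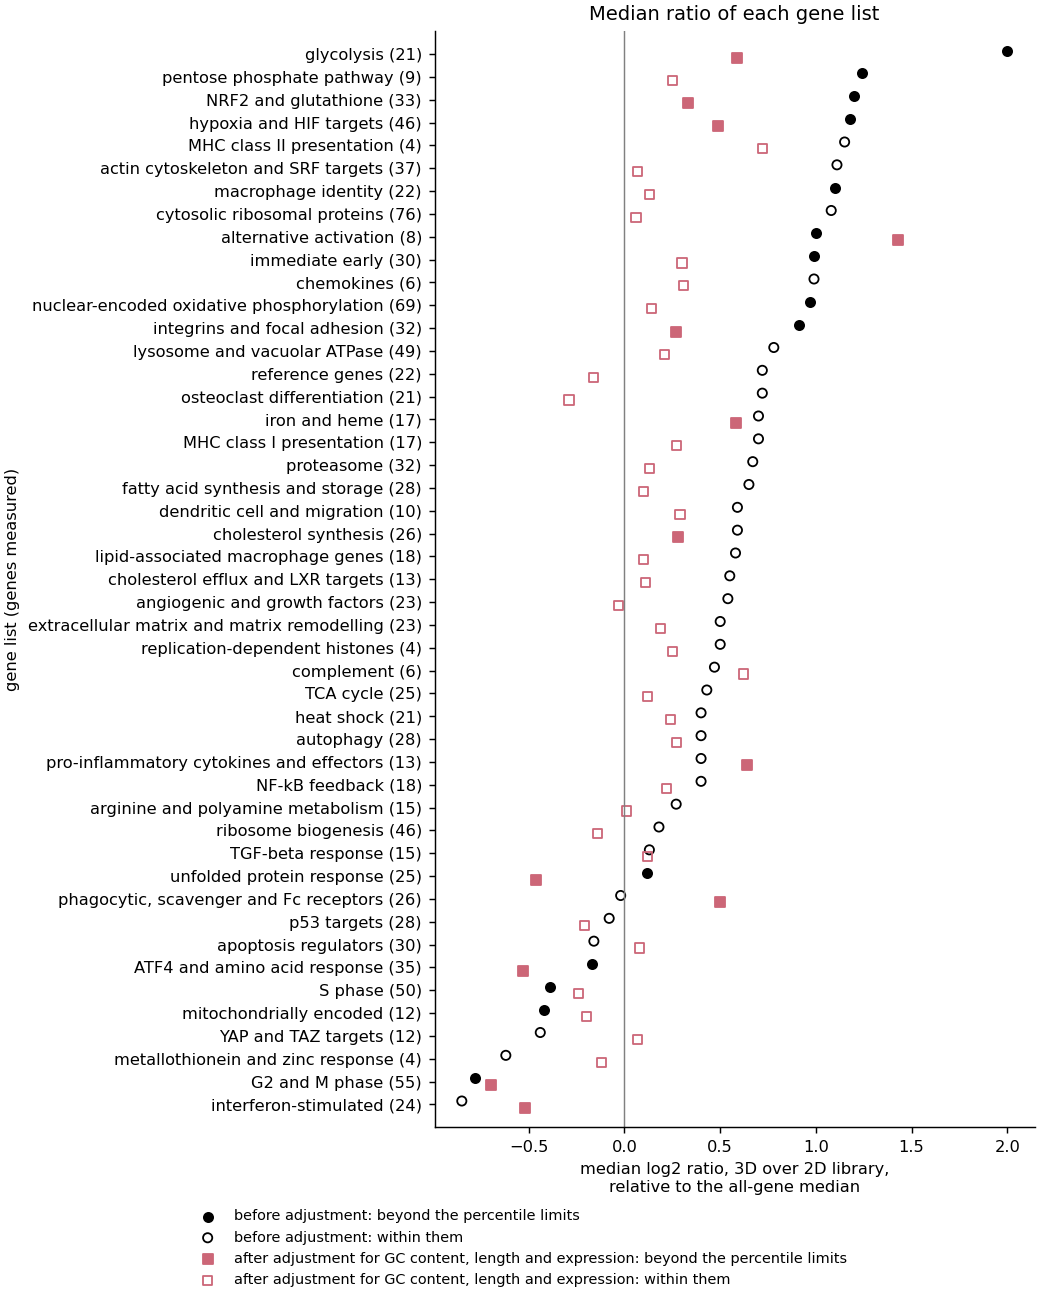
Median log2 ratio of the 3D library over the 2D library relative to the all-gene median (x axis) for the 47 gene lists with at least 4 measured members (y axis, with the number of measured genes). Circles are values before and squares after adjustment for GC content, exon length and expression, and filled symbols lie beyond the outer 2.5% of 10000 random lists on either side, as for glycolysis at 2.00 and 0.59 and the G2 and M phase list at -0.78 and -0.70.

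Most markers of other cell types had few counts in both libraries, and 1 T and NK cell marker, 3 endothelial markers and 2 mast cell and basophil markers were measured. The T and NK cell list held 102 counts in the 2D library and 105 in the 3D library, nearly all from Lck with 96 in each. The B cell list held 11 and 5 counts, the neutrophil list 22 and 27, the fibroblast and stromal list 41 and 34, the epithelial list 6 and 16 and the erythroid list 13 and 14. The endothelial list held 440 and 815 counts, of which 357 and 714 came from Vwf, 2.61-fold higher in the 3D library (2.30 to 2.98). The mast cell and basophil list held 1219 and 1094, of which 865 and 795 came from Gata2 and 345 and 299 from Hdc. Across all lists, 9 of the 47 with a percentile lay above the limits and 5 below before adjustment, and 9 and 4 did after it, where about 2.4 would be expected by chance if genes moved independently. Of these, 5 lists lay above the limits in both cases, namely glycolysis, hypoxia and HIF targets, NRF2 and glutathione, alternative activation, and integrins and focal adhesion. The 3 below in both were G2 and M phase, unfolded protein response, and ATF4 and amino acid response. Lists that share genes, such as glycolysis with HIF targets or NRF2 with iron and heme, are not separate results in these tallies. The alternative activation list rested on 8 measured genes, while its members Arg1, Mrc1, Chil3, Retnla and Il10 had at most 4 counts in either library. For the lists described above by their unadjusted median alone, adjusted relative medians ran from -0.21 for p53 targets to 0.72 for MHC class II presentation, all within the limits. The sign turned for YAP and TAZ targets (0.07), apoptosis regulators (0.08), angiogenic and growth factors (-0.03) and ribosome biogenesis (-0.14).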

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

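Of the alternatives below, the adjustment for GC content, exon length and expression and the scaling to reference genes were chosen after seeing the data. The counts of 2181 higher and 2426 lower genes stayed within 1.5 times of these values under DESeq2 size factors, upper-quartile scaling, a mean of at least 5 CPM, a pseudocount, the interval bound and thinning, between 1533 and 2247 for higher and 1680 and 2449 for lower genes. Total counts gave 657 higher and 4292 lower genes, and reference gene scaling gave 416 and 4704, since these scalings shift all ratios down. Without a filter 3939 genes were lower, with 15192 genes entering. The 1.5-fold threshold gave 3701 higher genes, and the 4-fold threshold gave 260 higher and 779 lower genes. After adjustment 1227 genes were higher and 1138 lower.

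Under DESeq2 size factors and upper-quartile scaling, all 47 lists kept their side of the percentile limits. Adjustment turned the relative median of the phagocytic, scavenger and Fc receptor list from -0.02 to 0.50 (percentile 99.8) and that of the unfolded protein response from 0.12 to -0.46 (percentile 0.3); the cause was not tested. It brought 6 lists within the limits: macrophage identity (0.13), the pentose phosphate pathway (0.25), nuclear-encoded oxidative phosphorylation (0.14), mitochondrially encoded genes (-0.20), S phase (-0.24, percentile 2.6) and immediate early genes (0.30). It took 5 beyond them: the phagocytic, scavenger and Fc receptor list above, inflammatory cytokines and effectors (0.64), interferon-stimulated genes (-0.52), cholesterol synthesis (0.28) and iron and heme (0.58). Other settings moved 5 lists across a limit. MHC class II presentation, at percentile 97.29, reached 97.6 under total counts, 98.5 with a pseudocount and 97.9 among protein-coding genes; actin and SRF targets, at 97.12, reached 98.4 under total counts, 98.0 without a filter and 98.4 with matching on exon length. Matching on exon length placed oxidative phosphorylation at 86.3, total counts placed the unfolded protein response at 2.8, and a mean of at least 5 CPM placed inflammatory cytokines at 98.2.

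Of 189 named genes, 10 at least 2-fold different turned direction after adjustment, with log2 ratios of -0.02 for Cd74, -0.09 for Cfp, -0.32 for Srm, -0.21 for Oaz1, -0.30 for Rpl36, 0.11 for Skil, 0.48 for Hist1h1d, -0.09 for Rplp0, -0.12 for Cd68 and -0.36 for Actb. Adjustment moved 149 others beyond their counting interval and total counts moved 163, ending the 2-fold calls of Nos2 (0.59), Igf1 (0.49) and Actb (0.56) among 33 of the 131 higher genes, and reference gene scaling ended 54. Leaving out a replicate was not possible with 1 library per culture method, and depth limits genes such as Arg1, Il1b, Il6 and Mrc1, which had at most 4 counts.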

Other observations

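Among low-count genes, a set for plasma proteins made by the liver stood out in the 3D library. Apart from Alb, the 31 genes of a list drawn up after Alb, Ahsg and Apoa1 had been seen held 138 counts in the 2D library and 423 in the 3D library. Of these, 26 had more counts in the 3D library, 2 had fewer and 3 had 0 in both, and 26 had at most 2 counts in the 2D library. Plg and Pzp each had 0 and 17 counts, Apob had 0 and 13, and Fetub had 0 and 9. Afp, with 85 and 180 counts, and Ambp, with 26 and 33, were already present in the 2D library, whereas Trf, the transferrin gene, had 0 in both and Apoa2 had 11 and 2. The whole list amounted to 10.2 counts per 1000000 in the 2D library and 39.3 in the 3D library, and neither hepatocyte RNA nor reads exchanged with a liver library was tested as the source.

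Of the tests that follow, those on noncoding genes, on the GC slope within complexes and on hypoxia targets were set down before their results were seen, and the others only after. AT-rich coding transcripts and long noncoding RNAs were lower in the 3D library, and a GC bias of library preparation is a candidate explanation. Genes of the same complex can be assumed to move together, so within the ribosomal protein, oxidative phosphorylation and proteasome lists the slope of the log2 ratio on GC content was taken over 177 genes. It was 0.67 per 10 percentage points of GC (95% interval 0.54 to 0.79), against 1.07 over all coding genes; a slope above 0.5 of the genome-wide value had been set as the outcome such a bias would give, and the lower bound only just met it. A trend fitted on protein-coding genes left the noncoding genes at an adjusted median of -1.13 (-1.39 to -1.01, 382 genes). This argues against that trend as the whole cause of their lower level. Vomeronasal receptor genes, 295 in all, had 7 counts in the 2D library, or 0.00481% of the counts per kb of the measured noncoding genes. These values argue against genomic DNA as the source of the noncoding counts. It is not fully excluded, since counts of genes with near-identical copies are uncertain here. More unspliced nuclear RNA in the 2D library may contribute. Pooled small nucleolar RNA genes had a log2 ratio of -2.41 (-2.70 to -2.13). This pooled value was not adjusted for GC content or exon length, so by itself it does not separate unspliced RNA from a GC bias. Whether the 2 libraries were prepared together and had equal RNA integrity is not known. Unspliced RNA and a GC bias both stay open, as does a difference in culture, untested.

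Of the cell cycle genes, those of the G2 and M phase list were lower in the 3D library as a set. The G2 and M phase list stayed at percentile 0.0 after adjustment for GC content, exon length and expression. The fitted trend is therefore not the whole cause, but a bias along these properties that the fit misses is not excluded. Fewer dividing cells in the 3D culture may be the source, and S phase genes would then be lower too. Their list lay at percentile 2.62 after adjustment, between the limits set for either outcome, so this explanation and an effect on mitotic genes alone cannot be told apart for the S phase genes at 1 library per culture method.

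Glycolytic genes were higher in the 3D library. Adjustment for GC content, exon length and expression lowered their relative median from 2.00 to 0.59, and the list stayed at percentile 99.98. The adjustment also removes biological differences along these properties, so the technical share of the fall was not tested. A hypoxia response in the 3D culture is a hypothesis: 32 targets of the hypoxia-inducible factors outside the glycolysis list had an adjusted median of 0.47, with 24 above 0, at percentile 100 of random lists. Before adjustment the median log2 ratio of these 32 targets was 0.44, with 12 at least 2-fold higher and 1 lower. That unadjusted median was not placed among random lists of like expression. The percentile therefore rests on the adjustment, which was chosen after seeing the data. The 32 targets are also part of the full hypoxia list, at adjusted percentile 100, so their result is not independent of it. Ddit4, Vegfa and Stc2, with adjusted log2 ratios of -1.43, -0.98 and -0.88, ran against the hypothesis. The targets Car9, Pfkfb3 and Ero1l were near equal before adjustment, at log2 ratios of 0.18, 0.14 and -0.04. Oxygen was not measured, and other inputs to glycolytic genes in the 3D culture stay open.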
